A study of Mus musculus with 6 samples.

How the data were processed

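Whole lung RNA was measured on 6 Affymetrix mouse 430 2.0 arrays, 2 for each of 3 genotypes on the BALB/c background. Each array held an RNA pool made from 4 mice, per the labels. The genotypes were wild type (WT), a knockout of the IL-4 receptor (IL4R KO), and the same knockout carrying a transgene that expresses the receptor from the SMP8 promoter, which the design text calls specific to smooth muscle (IL4R KO + SMP8-IL4R). Replicate numbers were taken from the labels.

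The values used were the log2 values deposited by the authors, made with RMA (robust multi-array average, which corrects background, applies quantile normalization and summarises the probes of each probe set), per the submitters' processing notes. The RMA version was not given in the sources used here. The log2 scale was checked on the values, which ran from 2.63 to 14.8. The largest gap between arrays at equal quantiles was 0.0649 on the log2 scale. RMA compresses small signals toward a floor, so fold changes of dim genes are uncertain. The table had no detection calls, so signal over background was judged by a gene's place among all values. The lower quartile of all values was 5.30, the median 7.10 and the upper quartile 8.98. No depth per sample exists for arrays, and their number limits the precision.

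The table held 45101 probe sets, of which 64 were array controls and were left out. The platform annotation gave 1 gene to 34958 probe sets, several genes to 932 and none to 9211, which were unnamed here. Of the probe sets with 1 gene, 34754 were matched by Entrez identifier to the reference gene table (assembly GRCm38.p6, used for names alone), and 0 symbols changed. Gene positions were not used here because no genome build is named for the arrays. Each of the 18194 genes was represented by its probe set with the highest mean over the 6 arrays. A gene was tested if that probe set lay above the median of all values in at least 2 arrays, which left 11861 genes. Probe sets ending in x_at or s_at can bind several related transcripts, so values of immunoglobulin genes such as Igkv9-120 and Igkv8-30 may mix family members. Chil4, Rnase2a, Ighg3 and Igkv6-14 were read by probe sets without these endings.

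Group means were compared with limma 3.58.1 in R 4.3.3, with 1 mean per group, all 6 arrays sharing 1 estimate of the spread, moderated variances without an intensity trend, and Benjamini-Hochberg adjustment over all genes tested. A gene passed at an adjusted p under 0.05. The fit had 3 residual degrees of freedom and 2.86 prior degrees of freedom. With 2 pools per group, p-values measure the spread between pools, and each pool averages over 4 mice. All printed adjusted p-values of genes come from this fit unless another is named. Comparisons were WT against IL4R KO, IL4R KO + SMP8-IL4R against IL4R KO, and IL4R KO + SMP8-IL4R against WT. Differences are given as the group named ahead minus the group named after it.

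Before the data were examined, 35 gene lists were fixed, with 473 distinct genes, of which 428 had a probe set. They covered goblet and mucous epithelium, alternatively activated macrophages, chemokines, the IL-4 and IL-13 receptor pathway, smooth muscle contraction, airway tone, matrix, complement and acute phase, interferon, cell cycle, immediate early and heat shock genes, circadian clock, sex-linked genes and cell types that a lung sample could hold. The 29 lists with at least 3 tested members were compared with all other genes by camera with a preset correlation of 0.01. This was repeated with an estimated correlation. That version also tests on the 3 residual degrees of freedom, so a list can fail it even at a low correlation. The fry test asked whether each list moved on balance one way. Benjamini-Hochberg adjustment ran over the 29 lists within each comparison. Named genes followed a rule fixed in advance. In each comparison these were the 10 largest rises and 10 largest falls among passing genes whose groups did not overlap, Il4ra, and up to 4 tested members of each list with the lowest p. Where fewer than 5 genes passed in a direction, the next genes by p up to 5 were given as not passing.

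The share of the WT response present in the transgenic lungs was the median, over genes passing in WT against IL4R KO, of the transgenic difference from IL4R KO divided by the WT difference from IL4R KO. Because both differences use the same IL4R KO arrays, it was set beside 100 simulations of an unchanged transgenic group.

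The pipeline was tested on simulated data for WT against IL4R KO, over 11861 genes in 10 runs with 1 spread for all groups and independent genes. The test recovered 54.6% of genes changed by 0.5 on the log2 scale, 90.4% of those changed by 1, 98.4% by 2 and 99.8% by 4, and 4.43% of calls were false. A list of 20 genes shifted by 0.4 was called in 100% of runs, and 0.345% of unshifted lists were called. Unequal spread and correlated genes were not simulated.

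Alternatives covered the filter on dim genes, the choice of probe sets, median centring, quantile normalization, an offset of 50 on the linear scale, an intensity trend with and without robust moderation, fits on the 4 arrays of a comparison, a replicate block, a 1.5-fold minimum, the set test, and each array left out. After the data were examined, fits without the 2 arrays that held liver transcripts, with a hepatocyte score or a Y-linked score as covariate, and with crossed replicate numbers were added, as were a filter on the 4 arrays of a comparison and a split that gave each comparison with IL4R KO its own IL4R KO array.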

Results

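Adult BALB/c mice of 3 genotypes received 2 to 3 µg of IL-13, a type 2 cytokine that signals through the IL-4 receptor, into the trachea daily for 7 days. Lungs were taken 24 hours after the last dose. The groups were WT mice, IL4R KO mice and IL4R KO + SMP8-IL4R mice, whose receptor came from a smooth muscle promoter. Each group had 2 arrays, each from a pool of 4 mice. All groups received IL-13, so no comparison here is against untreated lung. Median log2 values of the arrays lay between 7.08 and 7.11. The difference between the 2 pools of a group had an SD across genes of 0.169 in IL4R KO + SMP8-IL4R, 0.340 in IL4R KO and 0.221 in WT, and 34, 123 and 44 genes differed between pools by over 2-fold.

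Liver and sex-linked transcripts differed between pools of a group. Albumin (Alb), chosen after its values were seen, had log2 values of 12.3 in IL4R KO pool 1 and 11.8 in WT pool 2, and between 5.68 and 5.93 in the other 4 arrays. Y-linked genes were low in IL4R KO pool 2, where Eif2s3y was 4.27, Kdm5d 3.33 and Uty 3.56, against at least 8.49, 7.11 and 6.89 in the other arrays. Xist, transcribed from the inactive X chromosome, was 7.93 in IL4R KO pool 1 and between 10.1 and 11.4 elsewhere. The sex-linked list did not pass in any comparison, with medians of 1.95, 1.75 and -0.05 and camera adjusted p of 0.177, 0.134 and 0.857. Without IL4R KO pool 1 it passed against IL4R KO in both comparisons, with medians of 4.17 in WT and 3.96 in transgenic lungs.

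**Figure D1:**
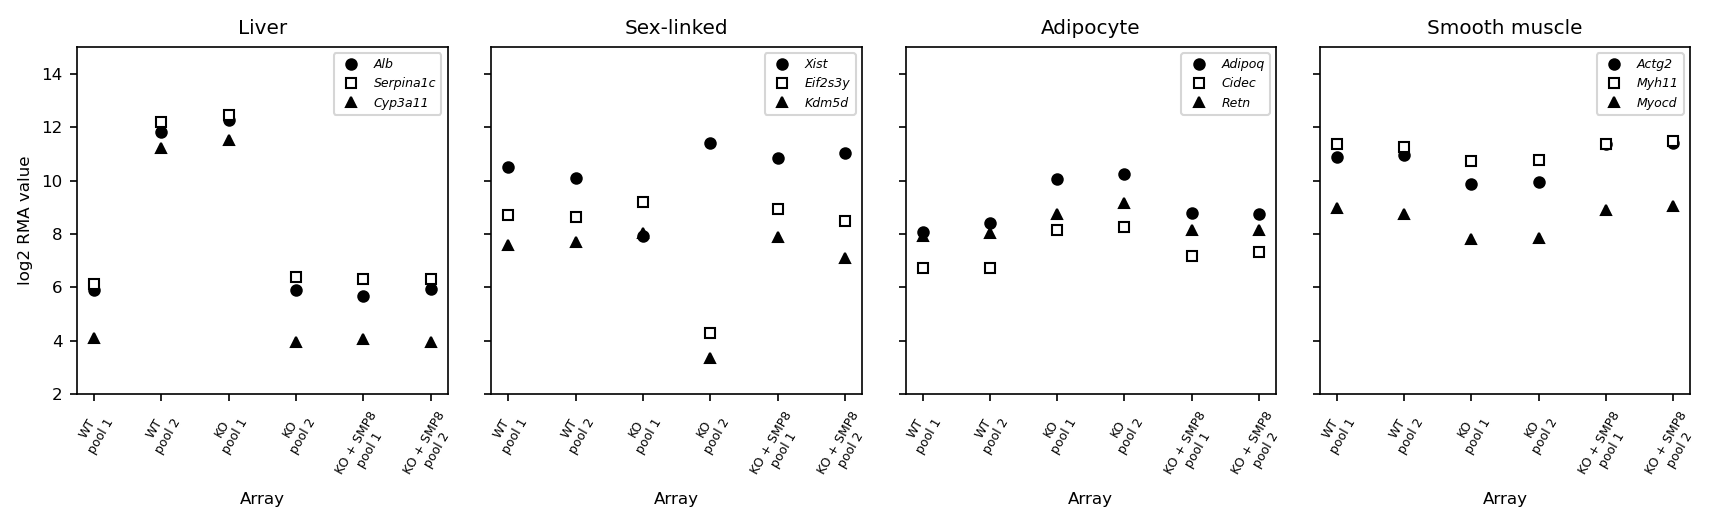
Log2 RMA values (vertical axis) of 3 liver, 3 sex-linked, 3 adipocyte and 3 smooth muscle genes in each of the 6 arrays (horizontal axis), 1 point per gene and array. Alb reached 12.3 in IL4R KO pool 1 and 11.8 in WT pool 2, Eif2s3y fell to 4.27 in IL4R KO pool 2, and Actg2 lay lower in both IL4R KO pools than in the other 4 arrays.

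The targeted gene, Il4ra, was read by 3 probe sets whose position relative to the deleted part and the transgene is not known here, so they do not check the labels. The brightest probe set gave 9.64 and 9.81 in the WT pools, 9.35 and 9.55 in IL4R KO, and 9.98 and 9.84 in IL4R KO + SMP8-IL4R. Its difference of 0.46 ± 0.11 (SE) between transgenic and IL4R KO lungs did not pass over 45037 probe sets (limma, adjusted p = 0.299). The next gave 9.23 and 9.29 in WT, 8.92 and 8.93 in IL4R KO, and 8.94 and 8.80 in transgenic lungs, and its difference of 0.33 ± 0.08 between WT and IL4R KO did not pass either (adjusted p = 0.123). The dimmest had values from 6.73 to 7.14.

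The comparison of WT with IL4R KO asked which transcripts depended on the receptor in any cell during IL-13 exposure. Secreted products of mucous epithelium and macrophages were among the transcripts with large differences. Clca1, a goblet cell secretory protein, had a mean of 14.3 ± 0.02 (SD, n = 2) in WT and 4.92 ± 0.49 in IL4R KO, a rise of 9.38 on the log2 scale (SE 0.34, limma adjusted p = 0.000191). The chitinase-like gene Chil4 rose by 8.64 (SE 0.06, adjusted p = 1.46e-07) and the ribonuclease gene Rnase2a, also known as Ear11, by 6.98 (SE 0.07, adjusted p = 8.51e-07). Further large rises were those of the anion exchanger Slc26a4 (5.77), Retnlb (5.77), the actin-severing Scin (5.32), Fer1l6 (4.72), the macrophage elastase Mmp12 (4.49), the lectin Itln1 (4.29) and Capn9 (4.27). The IL4R KO means of Clca1, Chil4, Retnlb, Fer1l6 and Capn9 lay below 5.30, the lower quartile of all values, so the size of their folds is uncertain. The other Clca1 probe set differed by 4.81. In all, 329 genes were higher and 228 lower in WT, of which 116 and 33 differed by over 2-fold.

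Of the goblet and mucous epithelium list, 13 of 14 tested members rose in WT, and 13 rose and 1 fell adjusted over the list alone. The median was 2.50 (camera adjusted p = 5.04e-23, adjusted p = 0.0598 with an estimated correlation), and the gel-forming mucin Muc5ac rose by 3.69 and Fcgbp by 2.83. Of the alternatively activated macrophage list, 14 of 18 rose (15 adjusted over the list alone), with a median of 1.85 (camera adjusted p = 6.40e-21, adjusted p = 0.124 with an estimated correlation). Among them the lectin Mgl2 rose by 2.11 and the checkpoint ligand Pdcd1lg2 by 2.05. Of 21 chemokines, 7 rose, and 10 rose and 2 fell adjusted over the list alone, with a median of 0.49 (camera adjusted p = 1.14e-05, adjusted p = 0.433 with an estimated correlation). The chemokine median was 0.89 without a filter or with a stricter one, and 0.80 with the median of probe sets. The eosinophil attractants Ccl11 and Ccl24 rose by 4.11 and 1.20, the T cell attractant Ccl17 by 2.96 and the neutrophil attractant Cxcl5 by 3.81. Of 14 receptor pathway genes, the feedback inhibitors Socs1 (0.74) and Cish (0.90) rose, and the list did not pass (camera adjusted p = 0.100; 3 rose and 1 fell adjusted over the list alone).

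Of 21 smooth muscle genes, 9 rose in WT, among them Actg2 (1.02), Synpo2 (1.00) and the transcriptional coactivator Myocd (1.03), and 2 fell, Casq2 (-0.63) and Pln (-0.43, named after its value was seen), calcium handling genes that are also expressed in heart. The counts were 12 and 2 adjusted over the list alone, with a median of 0.29 (camera adjusted p = 3.99e-06, adjusted p = 0.354 with an estimated correlation). With the median of probe sets the smooth muscle median was 0.11. Other probe sets gave values down to -0.27 for Synpo2, -0.14 for Tpm2, -0.052 for Myh11 and 0.40 for Myocd, and to -0.72 for Pln. Of 21 matrix genes, 8 rose (11 adjusted over the list alone), among them Igf1 (1.27), Col6a1 (0.91), Col5a2 (0.82) and Postn (0.83), with a median of 0.36 (camera adjusted p = 4.38e-08, adjusted p = 0.219 with an estimated correlation), which was 0.64 without IL4R KO pool 1. No cell cycle gene passed over all genes, 10 of 12 passed adjusted over the list alone, and the median was 0.69 (camera adjusted p = 1.71e-06, adjusted p = 0.433 with an estimated correlation), which was 0.42 without IL4R KO pool 2. Of 17 airway tone genes, Rgs5 rose by 1.06 while Ryr2 (-0.72) and Stim1 (-0.41) fell (5 rose and 5 fell adjusted over the list alone), and the list did not pass (camera adjusted p = 0.284). Their other probe sets gave as little as 0.59 for Rgs5, -0.28 for Ryr2 and -0.042 for Stim1.

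Immunoglobulin and adipocyte genes were among the transcripts that fell in WT. Ighg3 fell by 2.75 (SE 0.33, limma adjusted p = 0.0114), and Igkv9-120 (-2.32), Igkv8-30 (-2.21), Igkv6-14 (-1.74) and the immunoglobulin joining chain Jchain (-1.97) fell too. Other probe sets moved less, up to -0.09 for Ighg3 and -0.04 for Igkv9-120. Of the 11 probe sets of Ighm, which fell by 1.04, 4 moved the other way, up to 0.67. The paraoxonase Pon1 (-2.01), the endothelial proteoglycan Esm1 (-1.99), Krtap17-1 (-1.73) and the adipocyte genes Adipoq (-1.93) and Ucp1 (-1.70) fell as well. Without WT pool 1 or WT pool 2, Ighg3 (-2.63 and -2.87), Igkv9-120 (-2.09 and -2.55), Igkv8-30 (-2.28 and -2.13), Jchain (-1.92 and -2.02) and Krtap17-1 (-1.73 in both) no longer passed, nor did Esm1 (-1.85) and Ucp1 (-1.55) without WT pool 1. Igkv8-30 (-2.21) and Jchain (-1.97) did not pass without either transgenic pool or with a robust intensity trend, nor did Igkv9-120 with the median of probe sets (-1.83). Of 11 B cell and plasma cell genes, 4 fell (5 adjusted over the list alone), with a median of -0.57 (camera adjusted p = 6.79e-05, adjusted p = 0.220 with an estimated correlation). That median was -1.07 without IL4R KO pool 1, -0.25 without IL4R KO pool 2, -0.97 with a stricter filter, -1.05 without both arrays holding liver transcripts and -0.29 with a Y-linked covariate. Of 6 adipose genes, 4 fell (6 adjusted over the list alone), with a median of -1.22 (camera adjusted p = 1.21e-06, adjusted p = 0.369 with an estimated correlation). Of 11 cardiac muscle genes, 8 fell (10 adjusted over the list alone), including Myl7 (-0.88) and Tnni3 (-1.03), with a median of -0.74 (camera adjusted p = 2.89e-08, adjusted p = 0.394 with an estimated correlation). Sln, 1 of the 8, fell by 0.83, and its other probe set gave 0.15.

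Of 13 macrophage genes, 4 rose, such as Itgax (1.64), and 2 fell, among them Fabp4 (-1.52, and -0.67 by another probe set), with 7 and 3 adjusted over the list alone (median 0.34, camera adjusted p = 0.0226, adjusted p = 0.531 with an estimated correlation). The list did not pass without IL4R KO pool 2 (median 0.22) or without a filter (0.24). Lists that passed downward were mesothelium (median -0.34, 3 of 7 fell, 4 adjusted over the list alone, camera adjusted p = 0.00159), T cell (median -0.41, 1 of 8 fell, 3 adjusted over the list alone, adjusted p = 0.00292), skeletal muscle (median -0.36, 2 of 5 fell, 3 adjusted over the list alone, adjusted p = 0.00569) and fibroblast and pericyte (median -0.14, 1 of 12 fell, 4 adjusted over the list alone, adjusted p = 0.0446). With an estimated correlation, their adjusted p = 0.220, adjusted p = 0.531, adjusted p = 0.433 and adjusted p = 0.566. The fibroblast gene that fell, Dcn (-0.62), and the skeletal muscle gene Mb (-0.97) had other probe sets at 0.074 and 0.076. The T cell median was -0.19 without IL4R KO pool 2, the skeletal muscle list did not pass without IL4R KO pool 1 (-0.27) and had a median of -0.17 without a filter, and the fibroblast median was -0.24 without IL4R KO pool 1. The fibroblast list did not pass without IL4R KO pool 2 (-0.060) or WT pool 1 (-0.098), nor without a filter or with a stricter one (both -0.12). The complement, interferon, immediate early, circadian, dendritic cell, neutrophil, NK cell, ciliated, club, alveolar type 2, alveolar type 1 and endothelium lists did not pass, with camera adjusted p from 0.152 for the neutrophil list (median -1.07) to 0.853. Single arrays decided some of these calls. The neutrophil list passed without either transgenic pool (median -1.07) or IL4R KO pool 2 (-1.20), and the complement list without IL4R KO pool 1 (0.34). The NK cell, circadian and immediate early lists passed with medians of -0.97, 0.17 and 0.27 without IL4R KO pool 1, and of 0.51, -0.26 and -0.56 without IL4R KO pool 2. Within them the dendritic cell transcription factor Batf3 rose by 1.78, the secretory gene Bpifb1 by 1.28, the endothelial Vwf by 0.70 and the transcription factor Egr2 by 1.35, and the neutrophil granule gene Ltf fell by 1.07, the surface gene Itgae by 0.57, Lpcat1 by 0.56, Scgb3a2 by 0.54, Aqp5 by 0.41 and Hp by 0.38. Another Lpcat1 probe set gave -0.063. Of 12 club cell genes 1 rose and 4 fell, and of 7 dendritic cell genes 3 rose and 1 fell. Adjusted over the list alone, these counts were 2 and 4 for club, 3 and 1 for dendritic and 3 and 4 for alveolar type 2 cells, and at most 1 gene in each direction in the other 9 lists.

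Too few members were tested for a set test of the eosinophil, mast cell, type 2 lymphoid, red cell, thymus, and tracheal cartilage and thyroid lists, with 2, 1, 2, 2, 1 and 0 tested. In WT the lipoxygenase gene Alox15 rose by 0.93 and Icos fell by 0.39, where another Icos probe set gave -0.052. The values of Siglecf (-0.11), Kit (0.22), Rora (-0.31), Alas2 (-0.60), Slc4a1 (-0.47) and Cd1d1 (-0.34) did not pass over all genes. Adjusted over the list alone, 1 red cell gene and 1 thymus gene fell. No list passed camera with an estimated correlation, while 9 passed fry.

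Without 1 of the WT pools the count of 557 genes fell to 110 (pool 1) or 120 (pool 2), and it was 298 without either transgenic pool, 1512 without IL4R KO pool 1 and 1195 without IL4R KO pool 2. Single arrays also set the balance of directions. Without IL4R KO pool 1, 563 genes were higher and 949 lower in WT, and without IL4R KO pool 2, 663 and 532. Without WT pool 1 they were 88 and 22, without WT pool 2, 93 and 27, and without either transgenic pool 200 and 98. The fit with a Y-linked covariate called 1130 genes, and without both arrays holding liver transcripts the matrix and fibroblast medians were 0.60 and -0.26. With a Y-linked covariate the cell cycle and T cell medians were 0.44 and -0.25, and the macrophage (0.23) and fibroblast (-0.067) lists did not pass, nor did the fibroblast list with a hepatocyte covariate (-0.14). Leaving out a transgenic pool changes the shared spread alone, not the difference between WT and IL4R KO. Groups did not overlap for 51.6% of genes against 33.3% by chance.

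IL4R KO + SMP8-IL4R was compared with IL4R KO to ask what the receptor on smooth muscle changed. Of 21 smooth muscle genes, 5 were higher in the transgenic lungs (list adjusted p = 0.360 with an estimated correlation). Clca1, Chil4 and Rnase2a, which led the WT comparison, differed by -0.57, 0.15 and -0.028 and did not pass. Gamma smooth muscle actin, Actg2, had a mean of 11.4 ± 0.01 (SD, n = 2) in transgenic lungs and 9.91 ± 0.04 in IL4R KO, a rise of 1.48 (SE 0.06, limma adjusted p = 0.00473). The actin-binding Synpo2 rose by 1.31 (SE 0.08, adjusted p = 0.0136), the ATP receptor P2rx1 by 1.26, the G protein regulator Rgs5 by 1.17, Myocd by 1.13, the prolyl hydroxylase Egln3 by 1.13, tropomyosin Tpm2 by 0.75, the collagen Col8a1 by 0.73 and smooth muscle actin Acta2 by 0.65 (adjusted p = 0.0423). Adipoq fell by 1.39 (SE 0.12, adjusted p = 0.0423), and Tmem45b (-1.22) and the lipid droplet gene Cidec (-0.94) fell too.

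These 9 rises and 3 falls were all the genes that passed, and each also passed in the same direction in WT against IL4R KO. Next by p among genes lower in transgenic lungs were the ficolin gene Fcna (-0.87, adjusted p = 0.0616) and the atrial peptide gene Nppa (-2.35, adjusted p = 0.0693), which did not pass. Probe sets of a gene did not always move alike. Other probe sets gave 0.62 for P2rx1 and 0.48 for Myocd, and as little as 0.70 for Rgs5 and 0.39 for Col8a1. The 4 Synpo2 probe sets ranged from -0.28 to 1.31, the 4 of Tpm2 from -0.03 to 0.75 and the 3 of Acta2 from 0.26 to 1.13, and the median over Synpo2 probe sets was -0.14. Acta2 was read by a probe set that may bind related actins.

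**Figure D2:**
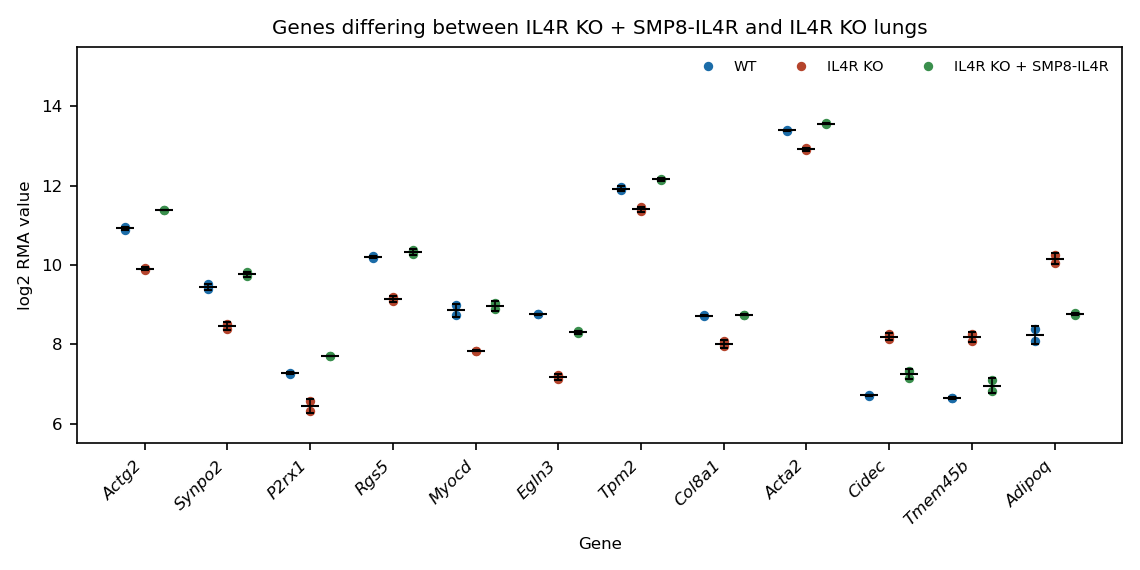
Log2 RMA values (vertical axis) of the 12 genes that passed between IL4R KO + SMP8-IL4R and IL4R KO (horizontal axis, ordered by difference), with points for the 2 pools per group and bars for the mean ± SD. Actg2 averaged 9.91 in IL4R KO, 10.9 in WT and 11.4 in transgenic lungs, while Adipoq averaged 10.2, 8.24 and 8.77.

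Of 21 smooth muscle genes, 5 rose, and 16 rose and 2 fell adjusted over the list alone, with a median of 0.43 (camera adjusted p = 3.03e-16, adjusted p = 0.360 with an estimated correlation, fry adjusted p = 0.0115). With the median of probe sets the smooth muscle median was 0.29. Of 17 airway tone genes 1 passed, Rgs5, while 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.258). No matrix gene passed over all genes, although 6 of 21 passed adjusted over the list alone (median 0.17, camera adjusted p = 0.000405, adjusted p = 0.360 with an estimated correlation), with values of 0.52 for Igf1 and 0.39 for Postn. The matrix list did not pass without IL4R KO pool 2 (median 0.12). No cell cycle gene passed, 4 of 12 did adjusted over the list alone, and the list's median was 0.54 (camera adjusted p = 2.55e-07, adjusted p = 0.527 with an estimated correlation). The cell cycle median was 0.29 without transgenic pool 1, 0.81 without IL4R KO pool 1 and 0.27 without IL4R KO pool 2.

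No gene of the goblet list passed, and the list had a median of -0.19 (1 fell adjusted over the list alone, camera adjusted p = 0.00872, adjusted p = 0.360 with an estimated correlation). Of its 14 members, 6 were tested because of their level in WT. Over the other 8, with a filter on the 4 arrays of the comparison chosen after the data were seen, the list did not pass (median -0.063, camera adjusted p = 0.166). The goblet median was -0.12 without transgenic pool 1 and -0.11 without a filter or with an offset of 50, and the list did not pass without IL4R KO pool 1, alone or with WT pool 2 (both -0.18). Tff2 differed by -0.60, Scin by -0.20 and Muc5ac by -0.18. The alternatively activated macrophage, chemokine, receptor pathway, complement and interferon lists did not pass, with medians of 0.05, 0.07, 0.11, 0.14 and 0.06 and camera adjusted p of 0.134, 0.148, 0.118, 0.418 and 0.295. Without transgenic pool 2 the first 4 of these passed, with medians of 0.14, 0.32, 0.18 and 0.26, and without IL4R KO pool 1 the alternatively activated macrophage (0.17) and complement (0.26) lists did. Only 2 of their members passed adjusted over the list alone, both chemokines. Ccl11 differed by 1.41 (SE 0.17, adjusted p = 0.0929 over all genes).

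Of 6 adipose genes, 2 fell, Adipoq and Cidec, and 5 adjusted over the list alone, with a median of -0.87 (camera adjusted p = 1.77e-08, adjusted p = 0.360 with an estimated correlation). No cardiac gene passed over all genes, 8 of 11 fell adjusted over the list alone, and the median was -0.50 (camera adjusted p = 4.50e-08, adjusted p = 0.527 with an estimated correlation), which was -0.32 without IL4R KO pool 1. The mesothelium (median -0.19, camera adjusted p = 0.00557), macrophage (-0.10, adjusted p = 0.00993), T cell (-0.27, adjusted p = 0.00218), ciliated (-0.20, adjusted p = 0.000545) and club cell (-0.05, adjusted p = 0.00872) lists also passed downward with no single gene passing over all genes. Adjusted over the list alone, 1, 1, 2, 0 and 3 of their genes fell. With an estimated correlation the mesothelium list had adjusted p = 0.360 and the other 4 had adjusted p = 0.527. Single arrays moved these 5 lists. The T cell median was -0.52 without IL4R KO pool 1, and the list did not pass without IL4R KO pool 2 (-0.020). The macrophage median was -0.22 without transgenic pool 1 and -0.18 without IL4R KO pool 2, and the list did not pass without transgenic pool 2 (-0.018) or IL4R KO pool 1 (0.0024), nor without a filter (-0.077) or with a stricter one (-0.053). The ciliated median was -0.33 without IL4R KO pool 1, with no pass without transgenic pool 1 (-0.12). The club cell median was -0.11 without transgenic pool 2, with no pass without transgenic pool 1 (-0.039) or IL4R KO pool 1 (-0.097), and the mesothelium median was -0.12 without IL4R KO pool 2.

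The immediate early, circadian, dendritic cell, neutrophil, NK cell, B cell and plasma cell, alveolar type 2, alveolar type 1, endothelium, fibroblast and skeletal muscle lists did not pass, with camera adjusted p from 0.0738 to 0.917. Some passed with 1 array left out. The NK cell, circadian and immediate early lists did so without IL4R KO pool 1 (medians of -0.77, 0.29 and 0.22) and without IL4R KO pool 2 (0.63, -0.17 and -0.64). The neutrophil list did without transgenic pool 1 (-0.75) or pool 2 (1.41), the B cell and plasma cell list without IL4R KO pool 1 (-0.47), and the skeletal muscle list without transgenic pool 2 or IL4R KO pool 2 (both -0.20). No gene of these lists passed over all genes, and 2 skeletal muscle genes and 1 alveolar type 1 gene fell adjusted over the list alone. In the lists too short for a set test, Alox15 (-0.58), Siglecf (0.08), Kit (0.05), Icos (0.05), Rora (-0.08), Slc4a1 (0.42), Alas2 (-0.12) and Cd1d1 (-0.02) did not pass over all genes. Adjusted over the list alone, 1 eosinophil gene fell.

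The count of 12 depended on single arrays, being 0 without either transgenic pool or either WT pool, 21 (9 higher and 12 lower, with 8 of the 12 genes) without IL4R KO pool 1 and 176 (88 in each direction) without IL4R KO pool 2, and 0 with the 4 arrays of the comparison alone (limma, 643 to 974 genes at an unadjusted p under 0.05 in the fits that called 0, against 1468 with 6 arrays). Leaving out a WT pool changes the shared spread alone, not this difference, and gives the same fit as the 4 arrays. The count was between 5 and 7 without a filter, with a stricter one, with other probe set choices and with median centring. It was 14 with a filter on the 4 arrays of the comparison, 8 (5 higher and 3 lower) after quantile normalization and 19 with a robust intensity trend. It was 5 with a hepatocyte covariate and 91 (42 higher and 49 lower) with a Y-linked covariate. Without both arrays holding liver transcripts the cell cycle, T cell, ciliated and cardiac medians were 0.81, -0.52, -0.33 and -0.32, and the macrophage (0.0024) and club cell (-0.097) lists did not pass. With a hepatocyte covariate the ciliated and club cell medians were -0.31 and -0.11 and the macrophage list did not pass (-0.017). With a Y-linked covariate the cell cycle, macrophage and T cell medians were 0.30, -0.19 and -0.074 and the matrix list did not pass (0.13).

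IL4R KO + SMP8-IL4R was also compared with WT, which carries the receptor outside smooth muscle too. Products of goblet cells and macrophages such as Clca1 and Chil4 were lower in the transgenic lungs, and immunoglobulin transcripts such as Ighg3 were higher. Of 337 genes that passed, 82 were higher and 255 lower in transgenic lungs. Clca1 averaged 4.35 ± 0.63 (SD, n = 2) in transgenic lungs and fell by 9.95 relative to WT (SE 0.34, limma adjusted p = 0.000141), and Chil4 (-8.48), Rnase2a (-7.01), Slc26a4 (-5.78), Scin (-5.51), Retnlb (-5.19), Fer1l6 (-4.90), Mmp12 (-4.59), Itln1 (-4.57) and Cxcl5 (-4.33) followed. The T cell attractant Cxcl9 rose by 2.82 (SE 0.46, adjusted p = 0.0382), although its 2 transgenic pools stood at 9.50 and 8.34 and its other probe set differed by 0.55. Ighg3 rose by 2.77, Esm1 by 2.29, Jchain by 2.15, Igkv6-14 by 1.97, Igkv8-30 by 1.95, Igkv9-120 by 1.89, the cytokine Il18 by 1.58, Pon1 by 1.54 and Igha by 1.44. Other probe sets differed by -4.91 for Clca1, and by as little as 0.14 for Ighg3 and 0.056 for Igkv9-120. The transgenic means of Clca1, Scin and Fer1l6 lay below 5.30, the lower quartile of all values, so the size of their folds is uncertain. Without any 1 of the transgenic or WT pools, Cxcl9 (2.24 to 3.40), Ighg3 (2.66 to 2.89), Jchain (1.93 to 2.37), Igkv8-30 (1.87 to 2.02), Igkv9-120 (1.66 to 2.12) and Igha (1.27 to 1.61) no longer passed, nor did Esm1 (2.15) and Pon1 (1.42) without WT pool 1. With a robust intensity trend Cxcl9, Jchain, Igkv8-30, Igkv9-120 and Igha did not pass, with a replicate block Igkv9-120 and Igha did not, and Igkv9-120 did not with the median of probe sets (1.41).

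Of 14 goblet genes, 13 fell, also adjusted over the list alone, with a median of -2.77 (camera adjusted p = 4.10e-29, adjusted p = 0.0422 with an estimated correlation). Of 18 alternatively activated macrophage genes, 13 fell (15 adjusted over the list alone), with a median of -1.55 (camera adjusted p = 3.51e-23, adjusted p = 0.107 with an estimated correlation). Of 21 chemokines, 7 fell, including Ccl17 and Ccl11 (both -2.70), and 2 rose, Cxcl9 and Ccl12 (1.10), with 9 and 4 adjusted over the list alone (median -0.84, camera adjusted p = 8.67e-05, adjusted p = 0.617 with an estimated correlation). The chemokine median was -0.17 without transgenic pool 2 and -0.37 without a filter. Of 21 matrix genes, 7 fell (9 adjusted over the list alone), among them Col6a1 (-0.74) and Igf1 (-0.76, and to -1.28 by other probe sets), with a median of -0.21 (camera adjusted p = 9.27e-06, adjusted p = 0.324 with an estimated correlation). Cish (-0.95) and Socs1 (-0.49) fell, 2 of 14 in their list also adjusted over the list alone (camera adjusted p = 0.701).

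Smooth muscle genes were slightly higher in transgenic than in WT lungs, with a median of 0.18 over 21 genes (camera adjusted p = 1.96e-05, adjusted p = 0.468 with an estimated correlation), although Actg2 (0.47) alone passed and 2 passed adjusted over the list alone. Of 11 B cell and plasma cell genes 4 were higher, also adjusted over the list alone (median 0.53, camera adjusted p = 0.000727, adjusted p = 0.324 with an estimated correlation), and the median was 0.23 with a hepatocyte covariate. Cardiac genes had a median of 0.29 with Myl7 (0.54) higher and Nppa (-1.55) lower (6 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0139), and adipose genes a median of 0.35 with Cidec (0.54) higher (3 adjusted over the list alone, camera adjusted p = 0.0468). With an estimated correlation both had adjusted p = 0.794. Neither passed without transgenic pool 2 (medians of 0.20 and 0.31) or either IL4R KO pool (0.29 and 0.35), nor did the adipose list without WT pool 1 (0.24) or with an offset of 50 (0.27). The adipose median was 0.17 without a filter, and with a filter on the 4 arrays of the comparison the list did not pass (0.17). With a Y-linked covariate neither passed (0.30 and 0.34), nor did the cardiac list without both arrays holding liver transcripts (0.22) or the adipose list with a hepatocyte covariate (0.30). Macrophage genes were lower, 4 of 13 with Itgax at -1.70 and 1 higher (8 and 2 adjusted over the list alone, median -0.33, camera adjusted p = 0.000110, adjusted p = 0.617 with an estimated correlation). No ciliated cell gene passed, also adjusted over the list alone, while the list had a median of -0.23 (camera adjusted p = 0.000107, adjusted p = 0.669 with an estimated correlation).

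The remaining lists tested did not pass, with camera adjusted p from 0.0905 for the neutrophil list (median 1.37) to 0.857 for the sex-linked list. The neutrophil list passed without transgenic pool 2 (2.82). Without transgenic pool 1 the cell cycle (-0.36), complement (-0.32), fibroblast (0.17) and skeletal muscle (0.35) lists passed, and the fibroblast list also without WT pool 2 (0.15). Within them Batf3 (-1.71), Bpifb1 (-1.72), the surface gene Lypd2 (-0.97), Vwf (-0.63), Egr2 (-1.50) and Upk1b (-0.46) fell, while Itgae (0.78), Lpcat1 (0.54), Scgb3a2 (0.50), Aqp5 (0.45) and Muc16 (0.38) rose. Over all genes, 2 rose and 2 fell among club, 1 and 3 among dendritic cell and 1 and 1 among mesothelium genes. Other probe sets gave -0.066 for Lpcat1, 0.34 for Itgae and -0.18 for Upk1b. Adjusted over the list alone, 4 rose and 3 fell among alveolar type 2, 4 and 2 among club, 3 and 1 among mesothelium, 2 and 3 among dendritic cell and 3 and 0 among fibroblast genes, and at most 2 in a direction in each other list. The neutrophil gene S100a8 had values of 13.6 and 10.6 in the 2 transgenic pools. In the lists too short for a set test, Alox15 fell by 1.51 and Icos rose by 0.44 (0.062 by another probe set), while Siglecf (0.19), Kit (-0.17), Rora (0.23), Alas2 (0.48), Slc4a1 (0.89) and Cd1d1 (0.32) did not pass over all genes.

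**Figure D3:**
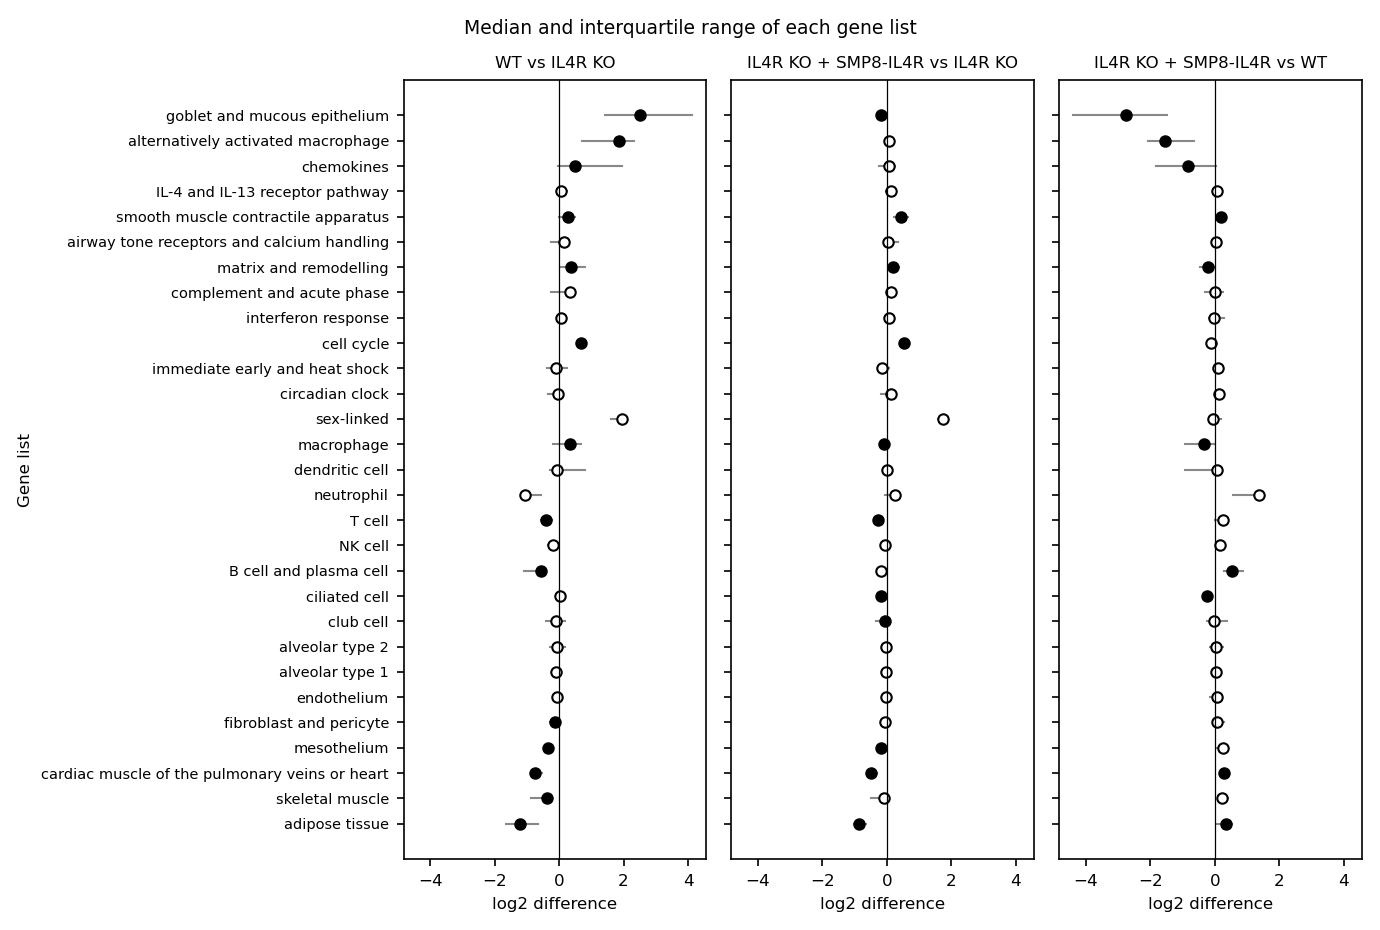
Median (point) and interquartile range (grey line) of the log2 difference (horizontal axis) over the tested members of each of 29 gene lists (vertical axis) in the 3 comparisons, with filled points at a camera adjusted p under 0.05 at the preset correlation. The goblet list had medians of 2.50, -0.19 and -2.77, and the smooth muscle list 0.29, 0.43 and 0.18.

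Leaving out 1 array gave 133 (transgenic pool 1), 117 (transgenic pool 2), 908 (either IL4R KO pool), 77 (WT pool 1) or 89 (WT pool 2) genes, against 337. Of these, 14, 19, 415, 3 and 9 were higher in transgenic lungs. Leaving out an IL4R KO pool changes the shared spread alone, not the difference between transgenic and WT lungs. The fit with a Y-linked covariate called 826 genes, and a 1.5-fold minimum left 223.

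Genes of the WT response differed in how far the transgenic lungs shared it. For the 329 genes higher in WT than in IL4R KO, the median share in transgenic lungs was 6.49% (interquartile range -7.38% to 31.7%), where unchanged simulated groups gave 4.79%. Among these, 9 also passed between transgenic and IL4R KO, and 218 passed between transgenic and WT. For the 228 genes lower in WT, the median share was 39.2% (20.1% to 57.9%) against 8.01% in simulations, 3 also passed between transgenic and IL4R KO, and 61 passed between transgenic and WT. These simulations used 1 spread per gene for all groups and independent genes, while pools differed by an SD of 0.340 in IL4R KO and 0.169 in transgenic lungs. Shared IL4R KO arrays may therefore give more than 8.01%. The 228 genes include 4 adipose and 8 cardiac genes, whose lists also fell in transgenic lungs (medians of -0.87 and -0.50). Tissue content of the IL4R KO pools was not separated from a shared response here. Independent lists would share 0.250 genes higher and 0.0577 lower, and simulations with shared arrays gave 0.09 and 0.16.

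With 1 array left out, the genes passing in WT against IL4R KO were chosen anew, so the shares cover different genes. The share of genes higher in WT was -1.56% without transgenic pool 1 and 8.79% without pool 2. It was -0.0666% without WT pool 1 and 0.335% without WT pool 2. It was 24.4% without IL4R KO pool 1 and 34.9% without IL4R KO pool 2, and that of genes lower in WT was 59.1% without IL4R KO pool 1. In these last fits 1 IL4R KO array was the control of both differences, which may raise the share. Across all genes the differences from IL4R KO correlated with r = 0.310 (rho = 0.496) and had a covariance of 0.0222. Simulations in which no group changed, WT included, gave a mean r of 0.752. Their mean covariance was 0.0291 (range 0.0212 to 0.0456), and the observed value minus that mean was -0.00696. The simulations left out the WT differences, so the r values are not a like comparison. The observed covariance lay within the simulated range, but that comparison is not like either. The simulated covariance takes in the gap between IL4R KO pools in liver transcripts, with a median of 4.18 over 20 hepatocyte genes. In the data these transcripts were also high in WT pool 2, by a median of 3.52 over pool 1, which lowers their WT difference. Genes are not independent replicates. In a split chosen after the data were seen, with IL4R KO pool 1 as the control of WT and pool 2 as that of the transgenic group, r was 0.0408 (rho = 0.0687) and the covariance 0.00352. With the pools exchanged, r was -0.144, rho was 0.0967 and the covariance was -0.0169. In that exchange liver transcripts, high in WT pool 2 and IL4R KO pool 1, rose in the WT difference and fell in the transgenic difference. They pull r and the covariance down, so these values do not measure a shared response. Part of any overlap may come from the shared arrays.

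**Figure D4:**
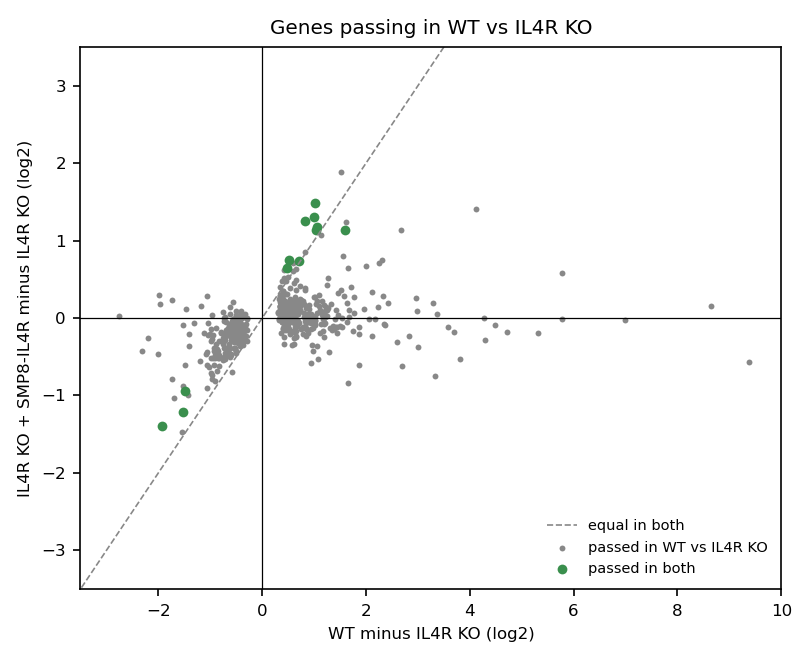
Log2 difference from IL4R KO in WT (horizontal axis) and in IL4R KO + SMP8-IL4R (vertical axis) for the 557 genes that passed in WT against IL4R KO, 1 point per gene, with the 12 that passed in both in green and a dashed line where both differences are equal. The genes with rises over 6 in WT, Clca1, Chil4 and Rnase2a, lay at -0.57, 0.15 and -0.03 in transgenic lungs.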

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

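The liver, hepatocyte, Y-linked and crossed fits and the filter on the 4 arrays of a comparison were chosen after the data were seen. Arrays limit the tests to 3 residual degrees of freedom, 2 with a block or 1 array left out and 1 without both liver arrays, and a group left with 1 array was assumed to vary like the others. The dim end of the scale limits the folds. Counts for transgenic against IL4R KO, 12 genes, were 5 without a filter, 6 with a stricter filter, 7 with the median of probe sets, 6 with every probe set, 7 with median centring, 19 with a robust trend, 0 with 4 arrays, 5 with a hepatocyte covariate and 91 with a Y-linked covariate, and the last covariate is low in IL4R KO pool 2 alone. Counts for WT against IL4R KO, 557 genes, were 298 with 4 arrays, 317 at 1.5-fold and 1130 with a Y-linked covariate, and for transgenic against WT, 337 genes, they were 908, 223 and 826. Leaving out each array gave 110 to 1512, 0 to 176 and 77 to 908 genes in the 3 comparisons. Without both arrays holding liver transcripts the counts were 526 (45.6% higher), 10 and 286, and 295, 5 and 202 of those genes had passed before.

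Differences between replicate numbers 1 and 2 correlated across genes at 0.121 for transgenic and IL4R KO, and at -0.0875 for transgenic and WT. These 2 values gave little sign that replicate numbers pair the pools. For IL4R KO and WT the value was -0.509. Liver transcripts, high in IL4R KO pool 1 and WT pool 2, pull it down, so it cannot tell whether pools were paired. Crossed replicate numbers put these pools in the same block. A replicate block gave 482, 10 and 277 genes, of which 422, 6 and 255 had passed before, and a crossed block gave 545 in WT against IL4R KO, of which 398 had passed before.

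Lists passing fell from 14, 11 and 10 to 0, 0 and 1 with an estimated correlation and to 9, 1 and 6 with fry. They were 17 for transgenic against IL4R KO with a hepatocyte covariate. The fall with an estimated correlation does not measure correlation alone, because that test also uses the 3 residual degrees of freedom. In WT against IL4R KO the estimate was 0.0122 for the goblet list, -0.114 for mesothelium and 0.904 for cell cycle, and none of these lists passed. The share of genes higher in WT ranged from -1.56% to 34.9% without 1 array, and was -0.0666% without WT pool 1. That of genes lower in WT ranged from 35.2% to 59.1%. The genes were chosen anew in each of these fits. Synpo2 in transgenic against IL4R KO was -0.14 with the median of probe sets, whose probe sets disagree. In that comparison, leaving out 1 array moved the difference of the dimmest Il4ra probe set from -0.17 to 0.13, over 0 without transgenic pool 1 (0.073) or IL4R KO pool 2, and that of the next from -0.12 to 0.0068, over 0 without transgenic pool 2. The other planned settings, apart from leaving out arrays, left 451 values of named genes and 336 list medians on their side of the threshold, while 51 and 8 no longer passed, and leaving out 1 array left 218 and 191, while 94 and 19 no longer passed. The settings added after the data were seen left 193 and 126, while 15 and 14 no longer passed. All these counts cover only named genes and lists that passed with all 6 arrays at the main settings. Lists that passed only in another setting, such as with 1 array left out, are not counted. Fewer arrays or genes entered the fits with 4 arrays, stricter filters or probe set medians, and the cause of the other moves was not tested.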

Other observations

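The family counts and the genotype, sex, airway and dilution tests were chosen after the result was seen. Because the families were chosen after the calls were seen, no enrichment test is given for them. Of 14 immunoglobulin genes, which encode antibody chains, 8 fell in WT against IL4R KO and none rose, with a median of -1.55. In transgenic lungs 7 of the 14 stood higher than in WT, and 0 of 14 passed against IL4R KO (limma, 1 at an unadjusted p under 0.05, median -0.12). The directions of these calls held under median centring, quantile normalization and an offset of 50. Calls were lost in other settings, with Ighg3 at -2.63 and Igkv8-30 at -2.28 no longer passing without WT pool 1, and Igkv9-120 at -1.83 with the median of probe sets. Several of their probe sets bind related chains, so the genes are not independent.

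Of 21 C-type lectin genes tested, many of which encode receptors of macrophages and dendritic cells, 8 rose in WT against IL4R KO, among them Clec4a3 by 1.77, Clec4a2 by 1.72 and Clec4b1 by 1.42. The median over all 21 was 0.18, and 5 of the 21 belong to a list fixed in advance. The same 8 were lower in transgenic lungs than in WT, with Cd209e at -2.91 and a median over the 21 of -0.045, and 0 passed between transgenic and IL4R KO lungs (limma, 4 of 21 at an unadjusted p under 0.05). With median centring 7 rose in WT. Of 226 solute carriers, 15 rose and 2 fell in WT, with Slc6a20a at 2.98 and the glucose transporter Slc5a1 at 2.36. That was 7.52% of the family against 4.70% of all genes tested, and the family median was 0.0070, so no family response is read from it.

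Liver transcripts stood high in IL4R KO pool 1 and WT pool 2. Of 20 further hepatocyte genes chosen before their values were seen, 19 (95%) lay higher in both of these arrays than in the other pool of the genotype. The median gap between pools was 1.36 and the median difference between WT and IL4R KO was -0.16 (95% bootstrap interval over genes -0.32 to -0.03). Because the pattern was 1 high pool in each of these genotypes, a small difference between their means followed from it. It is no separate test of genotype. Liver tissue carried into these pools may be the source, with Alb at 12.3 and 11.8 against 5.93 or less elsewhere, while 5 of the 20 genes lay above the table's median in both transgenic pools. Nothing here shows how it got there.

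Of 21 smooth muscle genes, 9 were lower in IL4R KO than in WT and 5 lower than in transgenic lungs (list adjusted p = 0.354 and adjusted p = 0.360 with an estimated correlation), while Casq2 and Pln averaged higher in IL4R KO than in both. The pools of IL4R KO differed in Y-linked signal yet by a median of -0.057 over the list (interval -0.095 to 0.0096). Transgenic minus IL4R KO was 0.43, and 0.35 with a Y-linked covariate. That covariate was -3.55 in IL4R KO pool 2 and between 0.22 and 1.03 elsewhere, so it mostly sets this pool apart and cannot separate sex from it. The gap between IL4R KO pools gave no sign of sex as the source, but it set single pools against each other that also differed in liver transcripts. Ciliated and club cell genes had a median of -0.19 (interval -0.25 to -0.07), no sign of more airway in transgenic pools. Across other settings the ciliated median ran from -0.33 to -0.12 and the club cell median from -0.11 to -0.039. Alveolar and endothelial genes had a median of -0.019 (interval -0.051 to -0.0033), no sign of dilution. These intervals resample genes, which are not independent, and do not measure the spread between pools. Sex, airway and dilution are therefore not ruled out. An effect of the receptor on smooth muscle and more muscle from large vessels were not tested and stay open.

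Adipocyte transcripts stood high in both IL4R KO pools. Of 17 further adipocyte genes chosen before their values were seen, 14 (82.4%) had a higher mean in IL4R KO than in both other groups, with a median transgenic difference of -0.35. Fat tissue in these pools may be the source, although 11 of the 17 genes lay above the table's median in both transgenic pools. An effect of the genotype on fat around the airways was not tested and stays open.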
